A study of Homo sapiens with 12 samples.

How the data were processed

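RNA sequencing read counts per gene were analysed for 12 libraries of activated T lymphocytes from human peripheral blood. The labels name 3 donors and 4 treatments, with 1 library for each donor and treatment: PBS as the vehicle control, the chemokine CXCL11 (also called ITAC), the secreted phospholipase A2 PLA2G10, and CXCL11 together with PLA2G10. The dose, the duration of each treatment and the way the cells were activated are not given in the sources used here. Each library was placed in its group by its treatment label, and the replicate number stands for the donor. The title of 1 library disagreed with its own treatment and donor labels; that library was used by the latter and was also left out as an alternative.

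Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made from total RNA with a SMARTer mRNA-Seq kit. The submitters' processing notes name Trim Galore 0.5.0, HISAT2 2.1.0, StringTie 1.3.3b, DESeq2 1.22.1 and the genome build hg38, without a role for any of them. The annotation release, the use of strand, the rule for reads that fall in several genes and the model formula are not given in the sources used here. The deposited values are whole-number counts per gene, not scaled to library size, and no normalised table of the authors was used. Because strand use is not stated, reads of a gene and of an antisense or overlapping gene cannot be told apart, and the text names the overlapping gene for each gene called over all genes that shares an exon with one. Overlaps of the other named genes are not listed.

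The table held 58288 gene IDs. Of these, 58025 matched a symbol and a position in GENCODE release 29 on hg38, with versions ignored, and the 263 others held 0.0217% of all counts. Counts were 0 in all libraries for 25248 genes. XIST, TSIX and Y-linked genes were left out of all tests. Library totals ran from 32402087 to 48217143. A floor of 3 counts corresponded to 0.0622 to 0.0926 CPM (counts scaled to library size) depending on the library. Floors and counts cover counting error only, since the reads carried no stated molecular identifiers.

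Genes were kept by the filterByExpr function of edgeR (minimum count 10, minimum total count 15), which left 19677 genes. Libraries were scaled by TMM, and edgeR 4.0.16 fitted 1 quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) to all 12 libraries, so that the 4 groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. The 8 comparisons were CXCL11 vs PBS, PLA2G10 vs PBS, CXCL11+PLA2G10 vs PBS, CXCL11+PLA2G10 vs CXCL11, CXCL11+PLA2G10 vs PLA2G10, the PLA2G10 effect averaged over CXCL11, the CXCL11 effect averaged over PLA2G10, and their interaction. The model without a donor term was chosen before the data were examined, as were the comparisons, the gene lists, the rule for named genes and the alternatives described below, apart from those said to have been added.

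The labels tie the 4 libraries of a donor together, so the same model with the donor as a block was also fitted, and its values stand beside each result that it changes. Deviations from the group means correlated at 0.313 to 0.457 between libraries of the same donor and at −0.593 to −0.0597 between libraries of different donors. The deviations within a group cancel out, so negative values between donors are partly built in. The common biological coefficient of variation of edgeR was 0.307 without the block and 0.184 with it. Each library was counted as 1 replicate, since the labels give each its own donor and treatment.

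Gene lists numbered 37 and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), each adjusted over the lists of a comparison. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Members were also tested adjusted over the list alone. The lists covered T cell activation, cytokines, cytotoxic effectors, inhibitory receptors, immediate early genes of the T cell receptor response, chemokine receptors, adhesion, lipid synthesis, oxidation, storage and signalling, glycolysis, hypoxia, stress responses, interferon-stimulated genes, NF-kB targets, the cell cycle, p53 targets, T cell subsets, mitochondrially encoded transcripts, ribosomal proteins, and markers of T cells and of 6 other blood cell types.

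The text names genes by a fixed rule. Per comparison, up to 12 higher and 12 lower genes were taken by the size of the log2 fold change among those past the threshold with the donor block, with a mean of at least 5 CPM and the same direction in all 3 donors. Where fewer than 5 passed in a direction, the genes with the smallest p filled up to 5 and are said not to pass. List members past the threshold over the list alone were added, up to 6 per list, together with 20 genes fixed by name. HLA genes, antigen receptor segments and KIR genes were not named, and 3 further genes are not reported here.

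The alternatives chosen beforehand were the donor block, DESeq2 size factors in edgeR, no filter, at least 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, only the compared libraries in the fit, an absolute log2 fold change of at least 1, and each library or donor left out in turn. Alternatives added after the data had been seen were a loess offset per library on GC content and transcript length (span 0.3), limma voom, both with the block, and the block without PLA2G10 replicate 2, the library farthest from the others on the third principal component.

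The tests were tried on counts simulated from the real libraries with 200 changed genes. For the PLA2G10 effect averaged over CXCL11, edgeR without the block recovered 0%, 20%, 74% and 92% of the 50 genes changed by 0.25, 0.50, 1 and 2 on the log2 scale, with 0 false calls among 19087 genes. With the block it recovered 16%, 68%, 96% and 96%, with 10 false calls. The Wald test of DESeq2 with the block recovered 26%, 80%, 100% and 100%, with 50 false calls among 19677 genes. In regroupings of the real libraries within donors, added later, this test called 163 to 229 genes for the same effect. Its counts with the block may therefore hold many calls that regroupings also give. The pairwise comparisons were not regrouped with it. For PLA2G10 vs PBS the block recovered 2%, 30%, 84% and 94% in edgeR, with 7 false calls. A simulated list of 25 genes raised by 0.25 was called by all 3 list tests, and 0 of 40 unchanged lists were. The simulated genes were drawn independently of each other, so false calls from genes that vary together could not appear in these lists. R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9 were used.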

Results

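Transcript counts were measured by RNA sequencing in activated human T lymphocytes from the peripheral blood of 3 donors. Cells of each donor received PBS, CXCL11, PLA2G10, or CXCL11 with PLA2G10, which gave 3 libraries per group. CXCL11 is an interferon-inducible chemokine that attracts activated T cells through the receptor CXCR3. PLA2G10 is a secreted enzyme that releases fatty acids and lysophospholipids from membrane phospholipids. Total counts per library averaged 39911380 ± 7617673 in PBS, 40477536 ± 2221348 with CXCL11, 36675065 ± 5480198 with PLA2G10 and 36934711 ± 4825941 with both (SD, n = 3).

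Donors separated the libraries more than treatments did. The first principal component of log expression held 25.7% of the variance and the second 17.8%, and both parted donors. The third held 8.05% and set PLA2G10 replicate 2 apart, at −56.7. The noncoding RNAs RN7SK, RN7SL1 and RN7SL2 together took 5.70 ± 0.588% of counts in PBS, 4.86 ± 0.824% with CXCL11, 4.49 ± 0.401% with PLA2G10 and 4.46 ± 0.438% with both (SD, n = 3). Mitochondrially encoded transcripts took 4.02 ± 0.266%, 3.95 ± 0.330%, 3.97 ± 0.717% and 4.56 ± 0.621% in the same order.

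Receptors and effector genes of direct interest did not pass the threshold in any of the 8 comparisons. CXCR3, the receptor of CXCL11, was at 127 ± 10.5 CPM in PBS, 136 ± 22.6 with CXCL11 and 125 ± 22.2 with both (SD, n = 3). ACKR3, an atypical receptor that also binds CXCL11, stayed at 1.78 ± 0.316 CPM in PBS and 1.83 ± 0.623 with CXCL11. The log2 fold change with CXCL11, averaged over PLA2G10, was 0.06 ± 0.04 for CXCR3, 0.12 ± 0.03 for CXCR4, 0.12 ± 0.04 for the activation marker CD69, 0.09 ± 0.03 for the interleukin-2 receptor gene IL2RA and 0.04 ± 0.05 for IFNG (SE, donor block). With PLA2G10 it was −0.09 ± 0.04 for CXCR3, 0.07 ± 0.03 for CXCR4, 0.16 ± 0.04 for CD69, 0.02 ± 0.04 for the granzyme GZMB and −0.09 ± 0.07 for the inhibitory receptor PDCD1. PTGER4, a receptor of prostaglandin E2, had −0.36 ± 0.14 with PLA2G10 and 0.38 ± 0.14 with CXCL11. SCD, HMGCS1, CPT1A, PLIN2, ABCA1, ITGAL, PRF1 and MKI67 also did not pass. The PLA2G10 gene itself had 0 counts in all 12 libraries, which allows at most 0.00649 CPM over the pooled counts, and PLA2R1, a receptor of secreted phospholipases, had 10 counts in total and was not tested. Across the 18 tested genes fixed by name the smallest adjusted p of edgeR was 0.160 with the donor block (CD69, PLA2G10 averaged over CXCL11) and 0.9999 without it.

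The series asks how PLA2G10 alters activated T cells, and 1 comparison set the 6 libraries with PLA2G10 against the 6 without it. SLC16A6, a monocarboxylate transporter family member, rose with PLA2G10, at 7.76 ± 2.88 CPM in PBS, 6.68 ± 2.89 with CXCL11, 14.3 ± 5.98 with PLA2G10 and 14.2 ± 5.41 with both (SD, n = 3). ARRDC3, an arrestin-domain protein of membrane protein trafficking, rose from 90.4 ± 23.9 and 92.2 ± 24.3 CPM to 159 ± 16.6 and 165 ± 21.1. GPCPD1, which cleaves the phospholipid breakdown product glycerophosphocholine, rose from 98.1 ± 11.4 and 101 ± 10.6 CPM to 130 ± 9.82 and 127 ± 10.1. ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 80.6 ± 9.92 and 84.3 ± 8.10 CPM to 99.2 ± 12.2 and 104 ± 9.73. FASN, the fatty acid synthase, fell from 265 ± 53.8 and 277 ± 45.4 CPM to 234 ± 37.1 and 236 ± 43.1.

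These genes passed with the donor as a block. The log2 fold change was 0.99 ± 0.09 for SLC16A6 (ENSG00000108932.11, chromosome 17, 68267026 to 68291267), 0.86 ± 0.09 for ARRDC3 (ENSG00000113369.8, chromosome 5, 91368724 to 91383359), 0.37 ± 0.04 for GPCPD1 (ENSG00000125772.12, chromosome 20, 5544404 to 5611026), 0.30 ± 0.03 for ODC1 (ENSG00000115758.12, chromosome 2, 10439968 to 10448504) and −0.20 ± 0.03 for FASN (ENSG00000169710.8, chromosome 17, 82078333 to 82098332), with SE over 12 libraries. Their adjusted p from edgeR was 0.00825, 0.0156, 0.00825, 0.0104 and 0.0349 with the block, and 0.736, 0.448, 0.622, 0.679 and 1 without it. FASN also lost its call with the GC and length offset. Positions are those of GENCODE release 29 on hg38.

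Among the called genes were 3 C2H2 zinc finger genes of chromosome 19, which no fixed list covered and which were put together after the calls were seen. ZNF442 (12345949 to 12365905) had a log2 fold change of 0.89 ± 0.10, ZNF844 (12064699 to 12081565) of 0.54 ± 0.06 and ZNF441 (11767000 to 11784078) of 0.47 ± 0.06. The other genes that rose and were named by the rule were the amino acid transporter SLC43A2 at 0.48 ± 0.07, the phosphatase regulator PPP1R10 at 0.46 ± 0.06, the linker histone H1F0 at 0.40 ± 0.06, C7orf50 at 0.41 ± 0.06 and C22orf46 at 0.30 ± 0.04. Those that fell were the E-protein transcription factor TCF3 at −0.32 ± 0.05, the kinase PDIK1L at −0.32 ± 0.05, the amino acid transporter SLC38A2 at −0.28 ± 0.04, the tubulin TUBB4B at −0.23 ± 0.03, the microtubule-associated protein MAP7D1 at −0.23 ± 0.03 and the RNA helicase DDX3X at −0.22 ± 0.02. The adjusted p of edgeR for these genes lay between 0.0104 and 0.0449 with the block and between 0.0611 and 1 without it. SLC16A6 overlaps ARSG, ARRDC3 overlaps ARRDC3-AS1, C7orf50 overlaps GPR146, C22orf46 overlaps SNU13, MAP7D1 overlaps TRAPPC3 and TUBB4B overlaps FAM166A, so reads of these pairs may be shared between them.

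**Figure D1:**
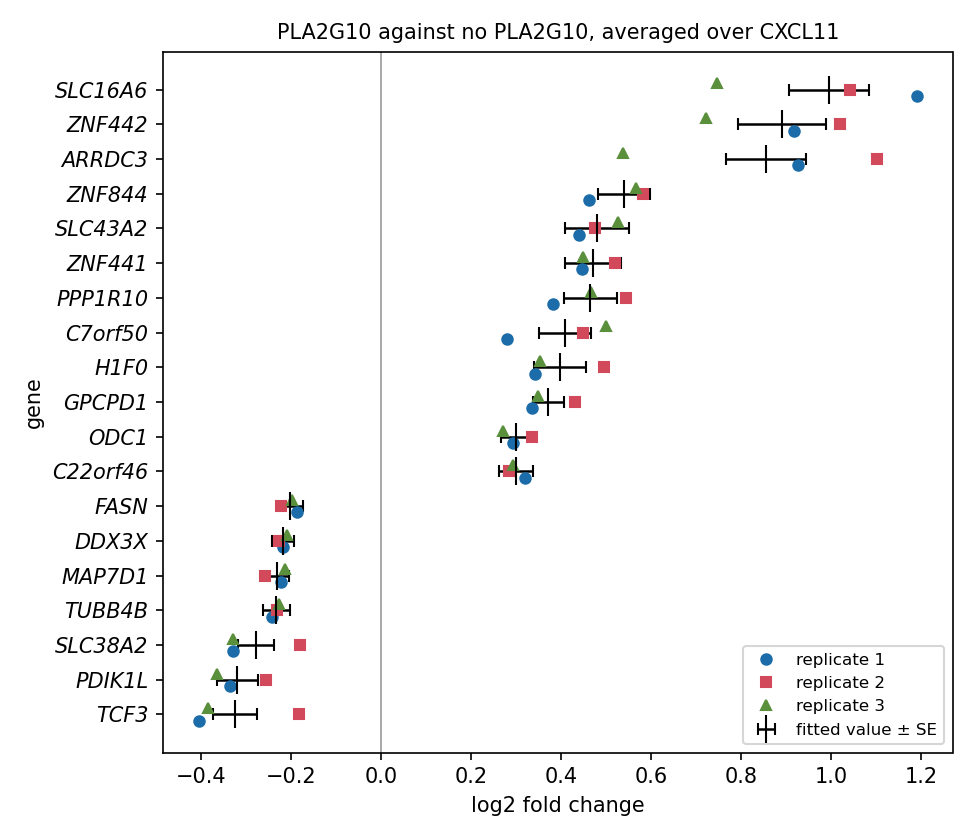
Log2 fold change of the 19 named genes called for PLA2G10 (horizontal axis), averaged over CXCL11, with the fitted value of the donor-blocked model and its SE (cross and bar) and the value of each replicate (symbols). Fitted values run from 0.99 for SLC16A6 to −0.32 for TCF3, and the same direction in all 3 replicates was required for a gene to be named.

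In all, 14 genes rose and 8 fell with PLA2G10 in edgeR with the donor block, and 2405 genes had an unadjusted p under 0.05. Without the block 1 gene passed (AL133415.1, lower) and 1079 had an unadjusted p under 0.05. The Wald test of DESeq2 called 458 genes with the block and 31 without it. The 22 called genes had a median absolute log2 fold change of 0.39. The 3 called genes outside the rule, named after their values were seen, were AL133415.1, AP001781.2 and the linker histone H1FX, which rose by 0.27 ± 0.04 and overlaps H1FX-AS1. AP001781.2 had 0 counts in PBS, 0 to 5 with CXCL11, 0 to 176 with PLA2G10 and 1 to 22 with both, and overlaps ALG9, C11orf1 and FDXACB1. Left-out libraries changed the blocked count: 6 genes passed without PLA2G10 replicate 2, 5 of them among the 22, 15 passed without CXCL11 replicate 3, 10 of them among the 22, and 9, 5 and 9 passed without donor 1, 2 or 3, with 1, 0 and 3 among the 22. Without the block the count was 0 without CXCL11+PLA2G10 replicate 2, 3 without CXCL11 replicate 1, and 2 without PBS replicate 1, CXCL11 replicate 2, PLA2G10 replicate 1 or PLA2G10 replicate 2.

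Genes of the G2 and M phases of the cell cycle were lower with PLA2G10. Of 26 members, 24 had a negative log2 fold change with a median of −0.12, and 14 fell when adjusted over the list alone, against 0 over all genes. Examples are the mitotic kinase PLK1 at −0.28 ± 0.06, the kinesin KIF20A at −0.28 ± 0.05, the cyclin-dependent kinase CDK1 at −0.24 ± 0.06 and the anaphase activator CDC20 at −0.23 ± 0.04 (SE, donor block). The proliferation marker MKI67 was at −0.01 ± 0.09. The camera test gave an adjusted p of 4.465e-10 with the block and 0.0184 without it. Camera with an estimated correlation gave an adjusted p of 0.439 with the block and 0.977 without it, and fry gave 0.0384 and 0.958. Without the donor block 0 of the members passed over the list alone, without donor 1, 2 or 3 the number was 8, 0 and 7, without CXCL11 replicate 3 it was 9 and without PLA2G10 replicate 2 it was 8.

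Fatty acid synthesis genes gave 2 of 21 members that fell when adjusted over the list alone, FASN and the elongase ELOVL1 at −0.23 ± 0.05. FASN alone was past the threshold over all genes, though not with the GC and length offset. Fry gave an adjusted p of 0.0384 for this list with the block, while camera gave 0.162 and an adjusted p of 0.439 with an estimated correlation. Further lists were lower by camera with the block: G1/S and S phase genes (22 of 24 members lower, adjusted p 9.343e-04), ribosomal proteins (36 of 41, 9.343e-04), glycolysis (17 of 22, 0.00338), the unfolded protein response (17 of 22, 0.00338), the heat shock response (14 of 18, 0.00751) and liver X receptor targets (10 of 12, 0.0185). At an estimated correlation these lists had an adjusted p of 0.635 for ribosomal proteins and 0.439 for the others. Without the block, camera called G2/M, ribosomal proteins (0.00660), the unfolded protein response and the heat shock response (both 0.0316), each with an adjusted p of 0.977 at an estimated correlation. The RN7SK, RN7SL1 and RN7SL2 share stood at 5.70% of counts in PBS against 4.49% with PLA2G10, beside these group differences. It was 4.86% with CXCL11 against 4.46% with both. Members past the threshold over the list alone were the replication and methylation factor UHRF1 at −0.19 ± 0.03, the chaperones HSPA5 at −0.13 ± 0.03, DNAJC3 at −0.17 ± 0.04 and DNAJA1 at −0.22 ± 0.04, and the glycolytic enzyme PFKP at −0.12 ± 0.03.

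Among immune and lipid signalling genes, list members past the threshold over the list alone with the block included CD69 at 0.16 ± 0.04 and ICOS at −0.10 ± 0.03 of 20 activation genes, and the chemokine receptors CCRL2 at 0.34 ± 0.10 and CXCR6 at −0.17 ± 0.05 of 14. The lysophospholipid receptors LPAR5, S1PR2 and S1PR4 had −0.21 ± 0.06, −0.17 ± 0.05 and −0.15 ± 0.04, as 3 of 17 members. Single members also passed in the lists of fatty acid oxidation (ACADVL at 0.25 ± 0.05), NRF2 targets (MAFG at −0.26 ± 0.06), NF-kB targets (TNFAIP8 at −0.23 ± 0.05) and memory T cell genes (ID3 at −0.27 ± 0.06). None of these members passed over all genes, and neither camera nor fry called these lists. The lysophospholipid receptor list had a median of 0.02 but a lower direction in camera, while the chemokine receptor and fatty acid oxidation lists had medians just under 0 and a higher direction.

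The remaining lists were not called for PLA2G10. Higher values were found in 7 of 22 cytokine genes, 7 of 16 cytotoxic effectors, 9 of 14 inhibitory receptors, 18 of 27 immediate early genes, 11 of 30 adhesion genes, 6 of 24 cholesterol synthesis genes, 12 of 26 lipid droplet genes, 14 of 26 eicosanoid genes, 9 of 21 phospholipase and remodelling genes and 7 of 19 hypoxia genes. The same held for 18 of 28 amino acid stress genes, 17 of 35 interferon-stimulated genes, 10 of 23 p53 targets, 11 of 25 helper and regulatory lineage genes and 12 of 15 mitochondrially encoded transcripts. Among marker lists, 4 of 16 T cell, 2 of 10 B cell, 3 of 6 monocyte, 4 of 12 natural killer cell, 1 of 2 dendritic cell, 0 of 2 platelet and erythroid and 5 of 5 neutrophil markers were higher. Mean marker levels with PBS and with PLA2G10 were 294 ± 16.0 and 284 ± 18.8 CPM for T cells, 5.33 ± 2.34 and 4.64 ± 2.03 for B cells, 6.24 ± 1.30 and 5.79 ± 0.516 for monocytes and 3.95 ± 1.25 and 3.96 ± 0.830 for natural killer cells (SD, n = 3).

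CXCL11 was compared with its absence over the 6 libraries with it and the 6 without it. FOSB, a subunit of the AP-1 transcription factor, rose with CXCL11, at 38.1 ± 6.10 CPM in PBS, 59.2 ± 15.2 with CXCL11, 41.7 ± 4.80 with PLA2G10 and 62.4 ± 3.21 with both (SD, n = 3). DDIT4, a stress-induced inhibitor of mTORC1, rose from 229 ± 22.5 and 245 ± 15.7 CPM to 319 ± 27.1 and 307 ± 10.9. BHLHE40, a transcription factor of activated T cells, rose from 1036 ± 175 and 1104 ± 148 CPM to 1352 ± 268 and 1347 ± 204. RGS16, which shortens G protein signalling, the transcription factor NFIL3 and TNFAIP3, an inhibitor of NF-kB signalling, rose too. No gene fell past the threshold over all genes in edgeR with all 12 libraries, while DESeq2 called 124 lower genes with the block and 3 without it. Regroupings within donors gave DESeq2 with the block up to 256 genes against the real 247. A further regrouping, which followed the real PLA2G10 groups, gave 392.

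The log2 fold change was 0.61 ± 0.07 for FOSB (ENSG00000125740.13, chromosome 19, 45467995 to 45475179), 0.43 ± 0.05 for RGS16 (chromosome 1, 182598623 to 182604408), 0.40 ± 0.04 for DDIT4 (chromosome 10, 72273920 to 72276036), 0.36 ± 0.04 for NFIL3 (chromosome 9, 91409045 to 91423862), 0.33 ± 0.04 for BHLHE40 (chromosome 3, 4979116 to 4985323) and 0.27 ± 0.03 for TNFAIP3 (chromosome 6, 137867188 to 137883312), with SE and the donor block. Their adjusted p from edgeR lay between 0.0256 and 0.0274 with the block and between 0.713 and 1 without it. DDIT4 overlaps DDIT4-AS1, BHLHE40 overlaps BHLHE40-AS1 and TNFAIP3 overlaps AL357060.1, so reads of these pairs may be shared. The lower genes with the smallest p, which did not pass, were CBFA2T2 at −0.38 ± 0.06, SEC61G at −0.38 ± 0.07, UBE2A at −0.29 ± 0.05, DIS3L2 at −0.24 ± 0.04 and CCM2 at −0.18 ± 0.03.

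**Figure D2:**
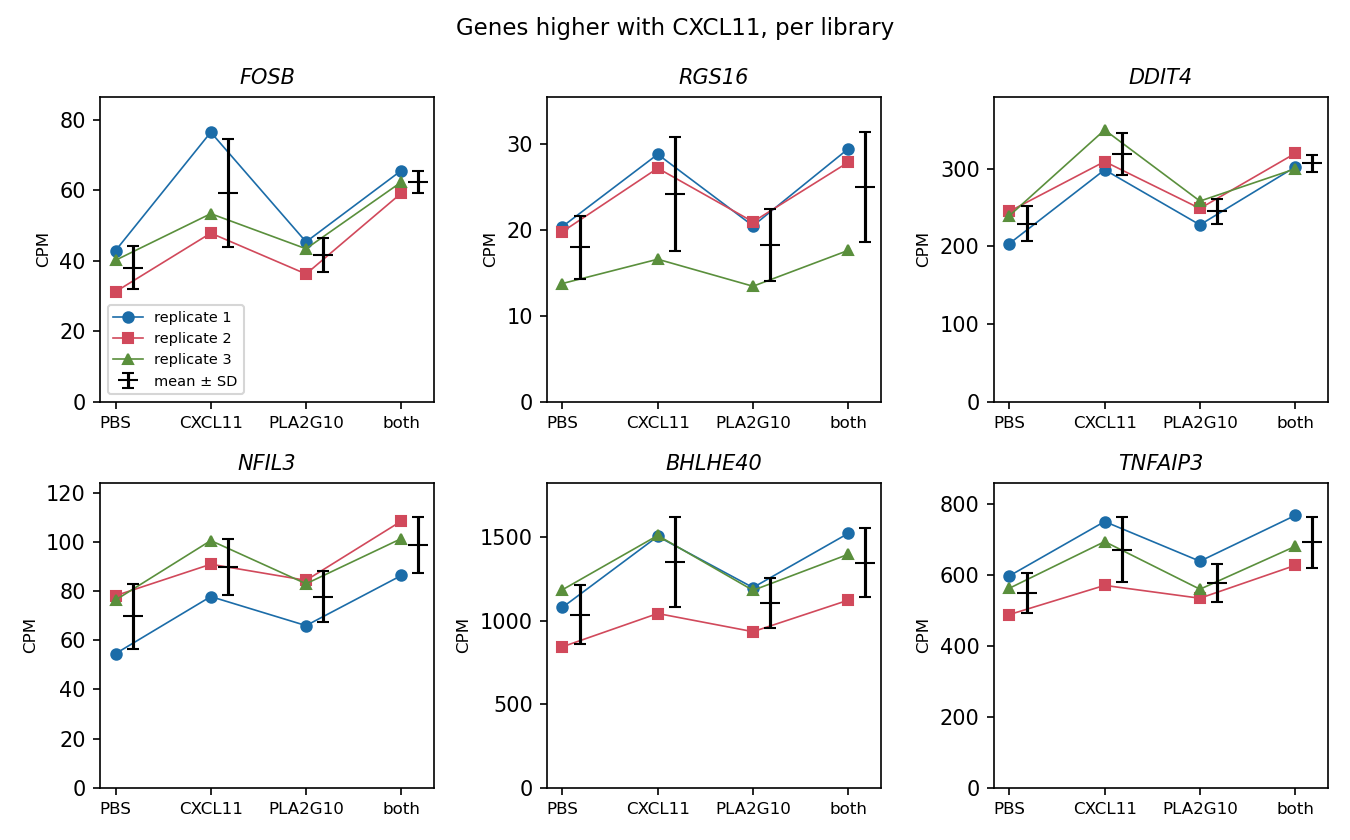
CPM (vertical axis) of 6 genes called for CXCL11 in each library of the 4 groups (horizontal axis), with lines joining the libraries of a replicate and bars for the group mean ± SD. For FOSB the group means are 59.2 CPM with CXCL11 and 38.1 with PBS, and the same direction in all 3 replicates, averaged over PLA2G10, was required for a gene to be named.

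In all, 7 genes rose with CXCL11 and 0 fell in edgeR with the donor block, and 1277 genes had an unadjusted p under 0.05. The called gene outside the rule was AL133415.1, at 1.04 CPM in PBS and 1.16 with CXCL11. Its averaged rise came from 0 counts with PLA2G10 alone, against 1.08 CPM with both. Without the block 1 gene passed (AL133415.1, higher) and 524 had an unadjusted p under 0.05. DESeq2 called 247 genes with the block and 9 without it. Leaving out CXCL11 replicate 3 left 1 gene, leaving out PLA2G10 replicate 2 left 1, and leaving out donor 1, 2 or 3 left 4, 5 and 2, with 0 of the 7 genes among them in each case. Of these, 1 was lower without CXCL11 replicate 3, 0 without PLA2G10 replicate 2, and 2 without donor 1, 2 or 3 in turn. Without the block the count was 2 without PBS replicate 1, any 1 of the CXCL11 libraries or CXCL11+PLA2G10 replicate 1.

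Immediate early genes, which T cell receptor signals switch on within minutes, were higher as a group. Of 27 members, 26 had a positive log2 fold change with a median of 0.20, and 16 rose when adjusted over the list alone, against 1 (FOSB) over all genes. Examples are the nuclear receptors NR4A1 at 0.64 ± 0.11 and NR4A3 at 0.46 ± 0.07, the transcription factor EGR1 at 0.36 ± 0.06 and the MAP kinase phosphatase DUSP5 at 0.27 ± 0.04 (SE, donor block). MYC was at −0.15 ± 0.82. The camera test gave an adjusted p of 3.346e-21 with the block and 1.787e-10 without it. Camera with an estimated correlation gave an adjusted p of 0.145 with the block and 0.369 without it, and fry gave 0.0240 and 0.315. Without the block 3 members passed over the list alone, and without donor 1 the number was 9.

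**Figure D3:**
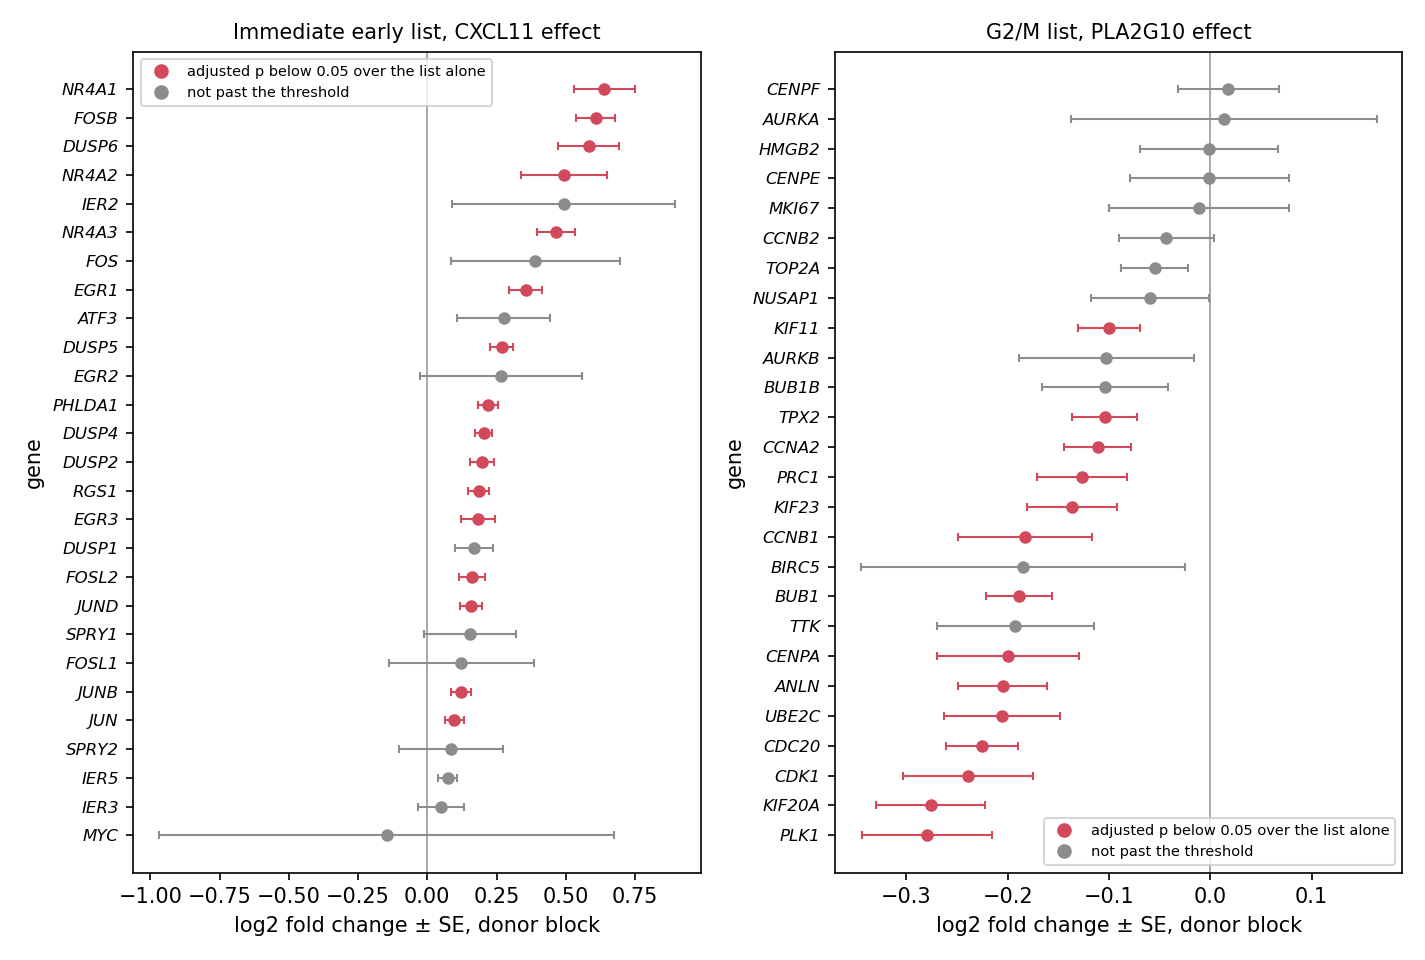
Log2 fold change ± SE with the donor block (horizontal axis) of the members of the immediate early list for CXCL11 (left) and of the G2/M list for PLA2G10 (right), each averaged over the other treatment. Points in red have an adjusted p below 0.05 over the list alone, as for 16 of 27 members on the left, all above 0, and 14 of 26 on the right, all below 0.

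Camera with the block also called NF-kB targets and adhesion genes for CXCL11. Of 20 NF-kB targets 16 were higher, with TNFAIP3 and NFKB2 (0.11 ± 0.03) past the threshold over the list alone and TNFAIP3 over all genes. Of 30 adhesion genes 19 were higher, with the lymphocyte egress receptor S1PR1 (0.19 ± 0.04) past the threshold over the list alone and 0 over all genes. With the block, camera gave an adjusted p of 0.00167 and 0.00552 and fry 0.0240 for both. The adjusted p with an estimated correlation was 0.145 for both, and without the block camera gave 0.0283 for both and fry 0.964 and 0.815. Without the block camera also called the heat shock response (0.0455) and mitochondrially encoded transcripts (0.0283), besides the immediate early list, and for the NF-kB, adhesion, heat shock and mitochondrial lists the adjusted p with an estimated correlation was then 0.816, 0.623, 0.816 and 0.853.

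With the block, camera called 15 lists, all higher, and fry 3. The 12 that fry did not call were T cell activation (16 of 20 members higher), cytokines (18 of 22), chemokine receptors (11 of 14), eicosanoid genes (19 of 26), lysophospholipid receptors (12 of 17), glycolysis (20 of 22), amino acid stress (18 of 28), the unfolded protein response (16 of 22), the heat shock response (14 of 18), mitochondrially encoded transcripts (14 of 15), ribosomal proteins (32 of 41) and T cell markers (13 of 16). Their camera adjusted p ran from 0.00110 to 0.0465. At an estimated correlation their adjusted p ran from 0.337 to 0.684. Members past the threshold over the list alone in these lists or in uncalled ones were the chaperones HSPE1 at 0.52 ± 0.12 and HSP90AA1 at 0.28 ± 0.07, the lineage factors GATA3 at 0.15 ± 0.04 and EOMES at −0.17 ± 0.05, and DDIT4 in the hypoxia and amino acid stress lists.

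The interaction asks whether the CXCL11 effect differed with and without PLA2G10. AL133415.1 (ENSG00000234961.1, chromosome 10, 17233325 to 17234833), an antisense transcript overlapping the intermediate filament gene VIM, had 35 to 57 counts in each of the 9 other libraries and 0 in all 3 libraries with PLA2G10 alone. Its level was 1.04 ± 0.114 CPM in PBS, 1.16 ± 0.159 with CXCL11 and 1.08 ± 0.192 with both (SD, n = 3), and it was at least 11.2-fold lower with PLA2G10 than in PBS, with 3 counts per library as the floor. VIM itself was at 1920 ± 283 CPM in PBS and 1731 ± 195 with PLA2G10. Because AL133415.1 overlaps VIM and strand use is not stated, its counts are uncertain. The interaction of AL133415.1 had an adjusted p of 0.00954 in edgeR without the block and 0.0810 with it, and 333 and 672 genes had an unadjusted p under 0.05. It was the only gene called, and DESeq2 called 13 without the block and 204 with it. Without PBS replicate 2, CXCL11 replicate 3 or CXCL11+PLA2G10 replicate 2 the count without the block was 0, without PBS replicate 1 it was 3, and without CXCL11 replicate 1, CXCL11 replicate 2 or CXCL11+PLA2G10 replicate 1 it was 2. With the block it was 5, 2 and 12 without donor 1, 2 and 3.

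Mitochondrially encoded transcripts were the only list called for the interaction. All 15 members had a positive value, with a median of 0.36 with the block, and 0 passed over the list alone or over all genes. Examples are MT-ND4L, a subunit of respiratory complex I, at 0.43 ± 0.13 and the ribosomal RNAs MT-RNR1 at 2.34 ± 1.34 and MT-RNR2 at 2.25 ± 1.35 (SE). Camera gave an adjusted p of 1.278e-06 without the block and 1.309e-11 with it. With an estimated correlation the adjusted p was 0.995 and 0.978, and fry gave 0.997 and 0.811. The neutrophil enzyme MPO, at 0.848 ± 0.652 CPM in PBS, had 1.71 ± 0.51 and passed only over its list of 5 with the block.

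CXCL11 vs PBS compared the chemokine alone with the vehicle. TMEM120B, a membrane protein of adipocyte differentiation (ENSG00000188735.12, chromosome 12, 121712752 to 121783001), rose with CXCL11 from 4.32 ± 0.666 to 13.1 ± 2.02 CPM (SD, n = 3) and was at 10.1 ± 0.483 with PLA2G10 and 8.54 ± 2.05 with both. It overlaps RHOF, so its reads may be shared. Of 27 immediate early genes 26 were higher, with a median of 0.27, and 11 rose when adjusted over the list alone, among them NR4A1 at 0.81 ± 0.16, FOSB at 0.63 ± 0.10 and NR4A3 at 0.60 ± 0.10 (SE, donor block), against 0 over all genes. DDIT4 at 0.48 ± 0.06, BHLHE40 at 0.38 ± 0.06 and ZNF131 at 0.62 ± 0.09 had the next smallest p and did not pass, nor did KMT5A at −0.64 ± 0.10, HELLPAR, YPEL2, PSMD2 and RASSF2 among the lower genes. S1PR1, TNFAIP3, the glycolytic enzyme PFKL, the chaperone CANX and DDIT4 passed over their lists alone and not over all genes.

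TMEM120B was the only gene called with the block, at a log2 fold change of 1.60 ± 0.16 and an adjusted p of 0.0338 in edgeR, against 0.122 and 0 genes without the block, and its adjusted p ran from 1.393e-12 to 0.227 over the alternatives. With the block 1069 genes had an unadjusted p under 0.05 and without it 467, and DESeq2 called 379 and 7. The TMEM120B call was lost without donor 1, 2 or 3 (adjusted p 0.0736, 0.227 and 0.158), without CXCL11 replicate 3 (0.121), at 5 CPM in 3 libraries (0.0712), with only the compared libraries (0.162) and with the GC and length offset (0.0515, log2 fold change 1.56). Camera called 9 lists with the block, all higher, and 2 without it, the immediate early list (adjusted p 2.896e-17 and 6.459e-08) and the adhesion list (0.00503 and 0.0284). The other 7 were T cell activation, liver X receptor targets, lysophospholipid receptors, glycolysis, amino acid stress, the unfolded protein response and NF-kB targets. With an estimated correlation the adjusted p with the block ran from 0.155 for adhesion and NF-kB to 0.542, with 0.215 for the immediate early list, and it was 0.606 for both lists without the block. Fry called adhesion and NF-kB at 0.0422 with the block and 0 lists without it. Without the block 1 gene passed without PBS replicate 1 or CXCL11 replicate 1, 2 without CXCL11 replicate 2 and 3 without PBS replicate 3, and with the block 3, 6 and 7 passed without donor 1, 2 and 3.

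PLA2G10 vs PBS compared the phospholipase alone with the vehicle. AL133415.1 fell to 0 counts, at an adjusted p of 0.00202 in edgeR without the block and 0.0192 with it. GPCPD1 at 0.41 ± 0.05, TMEM120B at 1.24 ± 0.16, ZNF844 at 0.57 ± 0.08, SLC16A6 at 0.87 ± 0.13 and ZNF442 at 0.92 ± 0.14 had the smallest p among higher genes and did not pass, with adjusted p between 0.0805 and 0.143 with the block. Among lower genes DDX3X at −0.23 ± 0.03, PDIK1L at −0.35 ± 0.06, the proteasome subunit PSMD2 at −0.28 ± 0.05 and MAP7D1 at −0.21 ± 0.04 did not pass. Of 26 G2/M genes 6 fell when adjusted over the list alone, among them KIF20A at −0.32 ± 0.08, ANLN at −0.25 ± 0.06 and BUB1 at −0.21 ± 0.05, against 0 over all genes. FASN, UHRF1, DNAJA1, TNFAIP8 and ID3 also fell over their lists alone and did not pass over all genes.

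AL133415.1, which the rule did not name, was the only gene called for PLA2G10 vs PBS with or without the block, while 1612 and 683 genes had an unadjusted p under 0.05 and DESeq2 called 444 and 12. Camera called 5 lists with the block, all lower: G2/M (adjusted p 2.261e-07), mitochondrially encoded transcripts and ribosomal proteins (both 0.00295), the heat shock response (0.00896) and G1/S genes (0.0382). Without the block it called 3, the mitochondrial and ribosomal lists (both 0.0236) and the heat shock response (0.0473). The adjusted p with an estimated correlation was 0.830 for all 5 lists with the block and 0.967 without it. Fry called 0 lists, with or without the block. Without the block 2 genes passed without PBS replicate 1, PLA2G10 replicate 1 or PLA2G10 replicate 2 and 3 without PBS replicate 3, and with the block 5, 2 and 12 passed without donor 1, 2 and 3 and 2 without PLA2G10 replicate 2.

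CXCL11+PLA2G10 vs PBS compared the combined treatment with the vehicle. Immediate early genes were higher, with 25 of 27 members positive, a median of 0.25 and 13 members that rose when adjusted over the list alone, among them NR4A1 at 0.84 ± 0.16, FOSB at 0.73 ± 0.10 and DUSP5 at 0.38 ± 0.06, against 0 over all genes. Of 26 G2/M genes 5 fell over the list alone, among them KIF20A at −0.28 ± 0.08 and BUB1 at −0.21 ± 0.05, against 0 over all genes. The chemokine receptors CCRL2 at 0.56 ± 0.14 and CXCR4 at 0.18 ± 0.05, as well as CD69 at 0.29 ± 0.06, GATA3 at 0.23 ± 0.05, S1PR1 at 0.22 ± 0.05, the chaperone HSPE1 at 0.63 ± 0.17, DDIT4 and TNFAIP3, passed over their lists alone and not over all genes, as did FASN, ELOVL1, LPAR5 and DNAJA1 among lower genes. NFIL3 at 0.51 ± 0.06, ODC1 at 0.37 ± 0.05, GPCPD1 at 0.38 ± 0.05 and TNFAIP3 at 0.33 ± 0.05 did not pass over all genes, nor did GOLT1B at −1.06 ± 0.14, SEC61G at −0.62 ± 0.10, FNIP1 at −0.29 ± 0.05 and CREBRF at −0.28 ± 0.05.

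For the combined treatment against PBS, edgeR called 0 genes with or without the block, at a smallest adjusted p of 0.0725 and 0.965, while 1686 and 663 genes had an unadjusted p under 0.05 and DESeq2 called 472 and 12. Camera called 3 lists with the block, immediate early genes (adjusted p 3.050e-13) and mitochondrially encoded transcripts (0.0145) higher and G2/M (1.536e-05) lower. Without the block it called the immediate early list alone (6.969e-06). With an estimated correlation the adjusted p with the block was 0.802 for the immediate early and G2/M lists and 0.854 for the mitochondrial list, and 0.977 for the immediate early list without the block. Fry called 0 lists. Without the block 1 gene passed without PBS replicate 1, 2 without PBS replicate 3 and 4 without CXCL11+PLA2G10 replicate 1, and with the block 3, 4 and 12 passed without donor 1, 2 and 3.

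CXCL11+PLA2G10 vs CXCL11 asked what PLA2G10 added to the chemokine. SLC16A6 at 1.12 ± 0.13, PPP1R10 at 0.62 ± 0.08, GPCPD1 at 0.33 ± 0.05, ODC1 at 0.30 ± 0.05 and ZNF442 at 0.86 ± 0.14 had the smallest p among higher genes and did not pass. GOLT1B, a Golgi transport protein, at −1.15 ± 0.14, MAP7D1 at −0.25 ± 0.04, TSPOAP1-AS1 at −0.45 ± 0.07, TUBB4B at −0.26 ± 0.04 and DDX3X at −0.21 ± 0.03 did not pass either. Over their lists alone, FASN at −0.23 ± 0.04 and ELOVL1 at −0.35 ± 0.08, the G1/S genes UHRF1 at −0.17 ± 0.04 and UNG at −0.60 ± 0.16, and 4 of 26 G2/M genes (CDC20, PLK1, UBE2C and BUB1) fell.

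In this comparison edgeR called 0 genes with or without the block, at a smallest adjusted p of 0.0814 and 1, while 1553 and 642 genes had an unadjusted p under 0.05 and DESeq2 called 430 and 14. Camera called 7 lists with the block: mitochondrially encoded transcripts higher (adjusted p 7.402e-06), and G2/M (1.541e-07), the unfolded protein response (8.174e-04), G1/S genes (0.00221), glycolysis and liver X receptor targets (both 0.00260) and ribosomal proteins (0.0330) lower. Without the block it called 3, the mitochondrial (0.0146), unfolded protein (0.0351) and G2/M (0.0375) lists. At an estimated correlation the adjusted p with the block ran from 0.410 to 0.790, and it was 0.985 without the block. Fry called fatty acid synthesis (0.0418) with the block and 0 lists without it. Without the block 1 gene passed without CXCL11+PLA2G10 replicate 1, 2 without CXCL11 replicate 1 or 2 and 3 without CXCL11+PLA2G10 replicate 2. With the block 4, 8 and 9 passed without donor 1, 2 and 3 and 1 without CXCL11 replicate 3.

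CXCL11+PLA2G10 vs PLA2G10 asked what the chemokine added to the phospholipase. AL133415.1 rose from 0 counts, at an adjusted p of 0.00188 in edgeR without the block and 0.0180 with it, and was chosen after its values were seen. Of 27 immediate early genes 24 were higher, with a median of 0.18, and 12 rose over the list alone, among them DUSP6 at 0.77 ± 0.15, FOSB at 0.59 ± 0.10 and EGR1 at 0.36 ± 0.08, against 0 over all genes. All 15 mitochondrially encoded transcripts were higher, with a median of 0.32, of which MT-ND4L at 0.37 ± 0.09 passed over the list alone. TSN at 0.86 ± 0.14, RGS16 at 0.44 ± 0.07, TNFAIP3 at 0.26 ± 0.05 and DDIT4 at 0.33 ± 0.06 did not pass over all genes, nor did GOLT1B at −1.10 ± 0.14, DIS3L2 at −0.39 ± 0.06, the autophagy gene ATG13 at −0.58 ± 0.11, CBFA2T2 and ZNF615.

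AL133415.1 was the only gene called here with or without the block, while 887 and 364 genes had an unadjusted p under 0.05 and DESeq2 called 383 and 14. Camera called 5 lists with the block, all higher: the immediate early and mitochondrial lists (both 1.043e-12), cytokines and the heat shock response (both 0.0162) and T cell activation (0.0454). Without the block it called 2, the mitochondrial list (1.332e-07) and the immediate early list (3.214e-05). With an estimated correlation the adjusted p with the block was 0.430 for the immediate early and mitochondrial lists and 0.537 for the others, and 0.910 for both lists without the block. Fry called 0 lists. Without the block 2 genes passed without PLA2G10 replicate 2, 4 without CXCL11+PLA2G10 replicate 1 and 3 without CXCL11+PLA2G10 replicate 2, and with the block 4, 5 and 9 passed without donor 1, 2 and 3 and 2 without PLA2G10 replicate 2.

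The PLA2G10 effect was also compared across genes between the libraries without CXCL11 and those with it, which share no library. Over 19677 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.0492, Spearman's rho was 0.182 and 59.9% of genes had the same sign. Over the 11360 genes with at least 5 CPM in 3 libraries these values were 0.0219, 0.295 and 63.5%. Of genes with an unadjusted p under 0.01 in both comparisons with the block, 74 had the same sign and 6 the opposite. For the CXCL11 effect r was 0.0830, rho was 0.102 and 55.5% of genes had the same sign, with 0.145, 0.149 and 57.3% at 5 CPM, and 23 genes against 2.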

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

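The look at the counts and overlaps of AL133415.1 was chosen only after its result was seen. The CXCL11 effect on AL133415.1 differed between cells with and without PLA2G10, by the interaction term of edgeR without the donor block (Benjamini-Hochberg adjusted p 0.00954). With the block the adjusted p was 0.0810. The gene had 0 counts in the 3 libraries with PLA2G10 alone and 35 to 57 counts in each library of the other groups. It overlaps VIM, and its counts are uncertain where strand use is not stated.

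Mitochondrially encoded transcripts differed in the same interaction as a list, at a camera adjusted p of 1.278e-06 without the block and 1.309e-11 with it. The adjusted p with an estimated correlation was 0.995 and 0.978, and fry gave 0.997 and 0.811. Their share of counts averaged 4.02 ± 0.266% in PBS, 3.95 ± 0.330% with CXCL11, 3.97 ± 0.717% with PLA2G10 and 4.56 ± 0.621% with both treatments (SD, n = 3). PLA2G10 replicate 2, the library set apart on the third principal component, had the lowest share of the 12 libraries, 3.26%, against 4.69% and 3.96% in the other libraries with PLA2G10 alone. Donor 2 also had the lowest share in PBS, 3.72%, and with CXCL11, 3.60%, but not with both, 4.21%. The highest share, 5.28%, was that of CXCL11+PLA2G10 replicate 1.

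For the interaction, 31 of 100 regroupings of the libraries without the block called as many genes as the real groups (1), so chance cannot be excluded, and the highest other regrouping called 784. With the block the real groups called 0 genes, a count that any regrouping reaches, so the 99 regroupings within donors decide nothing here. The highest other called 14.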

How the results depend on the processing

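The GC and length offset, limma voom and the fits without PLA2G10 replicate 2 were chosen only after the results were seen. Counts are called genes and p-values are adjusted. The comparisons follow in this order: CXCL11 vs PBS, PLA2G10 vs PBS, both vs PBS, both vs CXCL11, both vs PLA2G10, PLA2G10 averaged, CXCL11 averaged and the interaction. The cause of a change was not tested except where stated.

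Without the donor block edgeR called 0, 1, 0, 0, 1, 1, 1 and 1 genes. The donor block (pairing by replicate) gave 1, 1, 0, 0, 1, 22, 7 and 0. DESeq2 gave 7, 12, 12, 14, 14, 31, 9 and 13. At least 5 CPM in 3 libraries gave 0, 0, 0, 0, 0, 1, 0 and 0, since it removes AL133415.1, the gene called without it, and the 1 left is another gene. Size factors and no filter left these counts unchanged. With only the compared libraries the first 5 gave 1, 0, 0, 3 and 0. Leaving out 1 library gave ranges of 0 to 3, 1 to 3, 0 to 4, 0 to 3, 1 to 4, 0 to 3, 1 to 2 and 0 to 3.

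With the replicate block DESeq2 called 379, 444, 472, 430, 383, 458, 247 and 204 genes. At least 5 CPM in 3 libraries gave 0, 0, 0, 0, 0, 22, 6 and 0. No filter gave 24 for PLA2G10 averaged. With only the compared libraries the first 5 gave 2, 1, 1, 7 and 0. An absolute log2 fold change of at least 1 gave 1, 1, 0, 0, 1, 2, 1 and 0. The GC and length offset gave 0, 2, 1, 2, 1, 20, 7 and 0, and voom 1, 0, 0, 0, 0, 22, 8 and 0. Leaving out a donor, CXCL11 replicate 3 or PLA2G10 replicate 2 gave 0 to 7, 2 to 12, 3 to 12, 1 to 9, 2 to 9, 5 to 15, 1 to 5 and 1 to 12.

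Camera without the block called 2, 3, 1, 3, 2, 4, 5 and 1 lists, with the replicate block 9, 5, 3, 7, 5, 7, 15 and 1. With an estimated correlation it called 0 in each comparison, with or without the block. Fry called 0 in each without the block and 2, 0, 0, 1, 0, 2, 3 and 0 with it. For the immediate early list (CXCL11 averaged) the adjusted p was 1.787e-10 with camera, 0.369 with an estimated correlation and 0.315 with fry. With the block these were 3.346e-21, 0.145 and 0.0240. For the G2/M list (PLA2G10 averaged) they were 0.0184, 0.977 and 0.958, and 4.465e-10, 0.439 and 0.0384 with the block. Immediate early members past the threshold with the block numbered 16, against 3 with no replicate block and 9 to 19 without a donor or library. G2/M members numbered 14, against 0 with no replicate block, 10 at 5 CPM in 3 libraries and 0 to 9 without a donor or library.

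The correlation between separate libraries of the PLA2G10 effect was 0.0492, with 0.0219 at 5 CPM in 3 libraries and 0.0264 to 0.0593 without a donor. For CXCL11 it was 0.0830, with 0.145 at 5 CPM and 0.0224 to 0.102 without a donor. Of 26 named calls with the block, 26 were kept by DESeq2, voom, size factors and no filter, 24 at 5 CPM in 3 libraries and 23 with the GC and length offset. Without the block 0 were kept, without donor 1, 2 or 3 the numbers were 0, 0 and 2, without CXCL11 replicate 3 it was 9 and without PLA2G10 replicate 2 it was 4 of 25, since CXCL11 vs PBS was not run there. None of those run reversed. FASN had −0.20 ± 0.03 and an adjusted p of 0.0349 before the GC and length offset and −0.16 and 0.0509 after it, within a range of 4.531e-06 to 1 over its alternatives. Over all named genes 3289 values kept their call or stayed within 1 SE, 146 lost and 117 gained a call, 151 uncalled values moved by at least 1 SE, and 0 reversed. Apart from the calls named here and beside each result, the donor block changed no other call.

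The spread between libraries and the use of 3 donors limit what these counts can show. In genes with ample counts, the typical squared difference between libraries of a donor was 5.845 to 12.05 times that of sampling noise. Such libraries also differ in treatment. For libraries of the same group, which come from different donors, it was 11.37 to 23.78 times. In simulated counts for PLA2G10 averaged, edgeR with the block recovered 16%, 68%, 96% and 96% of genes changed by 0.25, 0.50, 1 and 2 on the log2 scale, and 0%, 20%, 74% and 92% without it. For PLA2G10 averaged, changes of 0.25 or less were therefore mostly not detectable with the block, and changes of 0.50 or less without it. For PLA2G10 vs PBS, changes of 0.50 were recovered in 30% of genes with the block and 4% without it. Recovery was not computed for the interaction. Depth was not varied in the simulation, and a floor of 3 counts stood at up to 0.0926 CPM. A range without a donor rests on 2 libraries per group.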

Other observations

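The split tests of the list medians, the regroupings with DESeq2, the look at how regroupings divided the donors and the fits without PLA2G10 replicate 2 or with the GC and length offset were chosen only after the results were seen, and the zinc finger set was chosen after its called members were seen. Zinc finger genes of chromosome 19, which mostly encode DNA-binding repressors, were higher with PLA2G10 beyond the 3 called members. Of 225 other genes named ZNF on this chromosome, 161 were higher, with a median log2 fold change of 0.08 with the donor block against 0.00 for all tested genes, and 34 higher against 6 lower had an unadjusted p under 0.05. The camera p was 2.248e-05, and p = 0.00143 with an estimated correlation. Near the called members, between 11000000 and 13000000, 14 of 22 were higher (median 0.09, p 0.00763, and p 0.0318 with an estimated correlation). Of the others on chromosome 19, 147 of 203 were higher (median 0.07, p 5.004e-05 and 0.00136), and of 218 on other chromosomes 128 (median 0.02, p 0.0894 and 0.0236), so a shift confined to chromosome 19 was not shown. These p-values are unadjusted, over the 4 sets looked at, of which the first joins the next 2.

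For these zinc finger genes the median of 0.0753 was reached by 1 of 99 regroupings within donors, the real groups, with 0.0611 as the highest other, but the set was chosen from calls in the real groups, so chance cannot be excluded. GC content is argued against as the whole cause by the median of 0.0850 after a GC and length offset, although these genes had a lower GC content (42.3% against 48.5%). The medians were 0.0580 in PLA2G10 vs PBS and 0.0713 in CXCL11+PLA2G10 vs CXCL11, which share no library. Both comparisons enter the averaged effect whose calls led to this set, so they are not independent support. Their medians were not compared with regroupings. An effect of PLA2G10 may explain the shift, as a hypothesis. Reads shared among similar zinc finger genes and RNA quality were not tested and stay open.

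The genes called for PLA2G10 with the donor block were weighed against technical causes. GC content and length are unlikely as the whole cause, since 90.9% of the 22 kept an adjusted p under 0.05 after the offset. The effect sizes had a median ratio of 1.001 without PLA2G10 replicate 2 to those with it. The 22 genes were called for a small spread over all libraries, that one included, so this ratio cannot decide whether 1 library stood apart. Without that library 6 genes were called, 5 of them among the 22. Of 394 genes with an unadjusted p under 0.01 in CXCL11+PLA2G10 vs CXCL11, 338 (85.8%) had the same direction in PLA2G10 vs PBS, which shares no library with it. Over all tested genes, in the fit without the block, 59.9% had the same sign in these comparisons. An effect of PLA2G10 may explain this, as a hypothesis. RNA quality was not tested and stays open. The RN7SK, RN7SL1 and RN7SL2 share was 5.70 ± 0.588% in PBS against 4.49 ± 0.401% with PLA2G10 (SD). In the libraries with CXCL11 it was 4.86 ± 0.824% without PLA2G10 against 4.46 ± 0.438% with it.

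The immediate early genes higher with CXCL11 were weighed against handling stress, which raises many of the same genes. The 15 handling genes had a median log2 fold change of 0.10 (0.0979), with 13 higher, but 7 of them belong to the immediate early list and the 8 others had a median of 0.05, so handling cannot be told apart from CXCL11 here. GC content and length are argued against as the whole cause by a list median of 0.18 after the offset, against 0.20 before it. With the offset 13 members passed over the list alone, against 16 before it. Camera at the preset correlation gave an adjusted p of 2.345e-20 after the offset. At an estimated correlation the list was not called even before it (adjusted p 0.145), so the preset p alone decides little. Of 160 genes with an unadjusted p under 0.01 in CXCL11+PLA2G10 vs PLA2G10, 109 (68.1%) had the same direction in CXCL11 vs PBS. These were taken from all tested genes, not from the list. Over all tested genes, in the fit without the block, 55.5% had the same sign. Handling of the libraries with CXCL11 could give the same agreement, so it cannot separate the causes. An effect of CXCL11 may explain the pattern, as a hypothesis, with handling open and RNA quality not tested.

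In edgeR, 1 of 99 regroupings within donors, the real groups, reached the 22 called PLA2G10 genes, with 5 as the highest other. The 7 called CXCL11 genes, AL133415.1 among them, were reached by 3 of 99, with 13 as the highest other. Counts this high were uncommon among regroupings with the block, which does not exclude chance for single genes. The regrouping with 13 followed the real PLA2G10 groups in all 3 donors and another, with 7, in 1 donor. With DESeq2 chance was not excluded for CXCL11, since a regrouping with 256 genes exceeded the real 247. Another, with 392, was the one with 13 in edgeR, which followed the real PLA2G10 groups. The median of the immediate early list with CXCL11 was reached by 1 of 99 (real 0.197, highest other 0.185) and that of the G2/M list with PLA2G10 by 3 of 99 (real 0.119, highest other 0.122). These lists were picked out of 37 for their results in the real groups, so chance cannot be excluded for them. Without the block, 37 of 100 regroupings called as many genes as the 1 for PLA2G10 and 39 of 100 as the 1 for CXCL11, so chance cannot be excluded. The highest other regroupings called 1031 and 315 genes. More than 10 genes were called by 2 of 16 and 2 of 15 regroupings that divided the donors most unevenly and by 0 of the others, which points to the donors as a structure of the libraries. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For CXCL11 vs PBS, PLA2G10 vs PBS, CXCL11+PLA2G10 vs PBS, CXCL11+PLA2G10 vs CXCL11 and CXCL11+PLA2G10 vs PLA2G10, the numbers of splits with as many genes were 10, 7, 10, 10 and 4. The real counts were 0, 1, 0, 0 and 1, and the highest others were 1, 4, 1, 2 and 2.

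DESeq2 with the block called 458 genes for PLA2G10 averaged, 247 for CXCL11 averaged and 204 for the interaction, against 163 to 229, 173 to 392 and 159 to 220 in 19 regroupings within donors. The 392 came from the regrouping that followed the real PLA2G10 groups, and the next highest was 256. The 200 genes whose counts jumped most between libraries of a donor had a median largest log2 range of 1.88 against 0.35 for 10765 others, among them AP002990.1, RN7SL5P and MT-RNR2. Their share with an exon overlapping another gene was 1.29 times (65% against 50.6%) and their median CPM 1.42 times that of the others.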
